A study of Mus musculus with 20 samples.

How the data were processed

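RNA of 20 livers was analysed, 5 from each of 4 genotype groups of female C57BL/6 mice aged 14 to 16 weeks. Per the labels' protocols, total RNA was extracted with RNeasy kits, libraries were made with a stranded total RNA kit after removal of ribosomal RNA, and they were read for 75 cycles on a NextSeq 500. Per the labels, the mice were matched for age and sex, and the transaldolase-deficient and double-deficient mice came from parents heterozygous at the Taldo1 locus. Genotypes were taken from the labels, and the titles give each liver a different animal number, so the replicates were treated as separate animals. The numbers do not repeat across groups, so no sample was paired by the labels.

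The authors deposited 1 table of estimated counts per gene, with 24453 genes and 1 column for each library. Per the submitters' processing notes, Bowtie and Cufflinks were among the tools and mm10 was the build; versions and roles are not given in the sources used here, nor is the tool that made the estimated counts. The labels' protocols name RPKM values, which the deposited table does not hold. Of its 489060 values, 32955 (6.74%) were not within 0.01 of a whole number, as happens where reads are divided among genes that share them. The 15 largest deposited estimated counts carry 3 significant digits only. Estimated counts were rounded to whole numbers before testing. Whether the counting used strand is not given in the sources used here, so a gene and an overlapping antisense partner may share reads, and families of near-identical copies share reads in an unknown way. The table holds 0 of the 13 mitochondrially encoded genes listed.

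The total per library ran from 8579989 to 18411515 estimated counts. At that depth Taldo1 had 211 to 1630 counts per library. Where a group had only a few counts of a gene in all, the change is given as a ratio of summed counts, scaled by library size, with a 95% interval that covers counting error only. Replicates were compared pair by pair before averaging, and none of the 40 pairs within groups agreed within sampling noise.

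Genes were filtered with filterByExpr by group, which left 13028 genes, scaled with TMM factors and tested with edgeR's quasi-likelihood F test in 1 fit over the 20 libraries, with a mean for each of the 4 groups. Contrasts were TALKO against WT, ARKO against WT, DKO against WT, DKO against ARKO, DKO against TALKO and the interaction, which is the effect of transaldolase loss without aldose reductase less that with it. P-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called when the adjusted p was under 0.05. The standard error of a log2 fold change is its size over the square root of F. CPM values use TMM-scaled library sizes, and a prior count of 2 entered only log2 CPM and principal components (1000 most variable genes). The software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

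Gene lists of pathways and cell types, 38 in all, were fixed before the data were examined, as were the tests, the groups, the rule for named genes and 60 alternatives. Taldo1 and Akr1b3 were left out of every list. The lists were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation beside it and with fry as an alternative, adjusted by Benjamini-Hochberg over the lists within a contrast. Of the 38 lists, 35 had at least 3 tested genes; mitochondrially encoded genes (0 in the table), pancreas (2 tested of 14) and Y-linked genes (0 tested of 4, used as a check of sex) were not tested as lists. Some lists share genes: the female-biased and P450 lists share 5, the pericentral and P450 lists 3, the fetal and cholangiocyte lists 2, and NRF2 targets share 1 with the P450 and 1 with the fetal list.

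The genes named are Taldo1 and Akr1b3; the 10 largest rises and the 10 largest falls of a contrast (5 of each for DKO against WT) among called genes with a mean of at least 1 CPM over the 20 libraries and every library of the first group on the same side of the mean log2 CPM of the second; up to 4 members of each list with the smallest adjusted p; and, for the interaction, the 5 genes with the smallest p where none passed. Gene models without a given name were counted but not named, and a gene named outside the rule is said to be chosen after its values were seen. The text gives part of the genes that the rule takes. Positions on mm10 come from the GENCODE mouse release 21 annotation (23405 genes placed by it, 306 by RefSeq symbol, 643 by RefSeq synonym, 99 not placed).

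Each test was run on simulated counts drawn from the libraries' means and sizes, with 200 genes changed, 100 by 1.5-fold and 100 by 2-fold. edgeR recovered 45% and 70% of them in TALKO against WT (12942 genes, 7 false calls), 36% and 74% in ARKO against WT (12946 genes, 4 false calls), 50% and 74% in DKO against WT (12936 genes, 5 false calls), 40% and 77% in DKO against ARKO (12924 genes, 9 false calls), 24% and 74% in DKO against TALKO (12940 genes, 2 false calls), and 10% and 43% for the interaction (12954 genes, 2 false calls). The alternatives were DESeq2, limma-voom, RLE factors, no filter on low counts (at least 1 count), a filter at a mean of 1 CPM, thresholds of 0.01 and 0.1 for overlaps, a fit of the 2 groups alone, animal number as a covariate, a block of livers with near animal numbers, overlaps without the genes within 10 Mb of the targeted genes, and each library left out in turn. A fit without 4 doubted libraries (WT replicates 1 and 2, TALKO replicate 1 and the library labelled ARKO replicate 1) was added after seeing the data.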

Results

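RNA was sequenced from the livers of 20 female C57BL/6 mice aged 14 to 16 weeks, in 4 genotype groups of 5. Wild-type (WT) mice carried both enzymes under study. TALKO mice lacked transaldolase, the enzyme of the non-oxidative pentose phosphate pathway encoded by Taldo1. ARKO mice lacked aldose reductase, the enzyme encoded by Akr1b3 that reduces glucose and other aldoses to sugar alcohols. Double-knockout (DKO) mice lacked both. The sample titles give each liver its own animal number, so the replicates were separate animals. The table of estimated counts held 24453 genes, and the total per library ran from 8579989 in WT replicate 1 to 18411515 in TALKO replicate 5. Of these genes, 13028 were tested, and they held 99.9% of the counts. The 40 pairs of libraries within groups correlated at Pearson r of 0.965 to 0.984 across genes, and each pair differed by more than counting error (chi-square per degree of freedom of at least 21.1). On the first principal component of the 1000 most variable genes (38.5% of their variance), the 10 WT and ARKO livers lay between -28.8 and -8.12, and the 10 TALKO and DKO livers between 2.25 and 29.96.

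The targeted genes were read first in each library. Taldo1 (chromosome 7, 141392199 to 141402968 on mm10) stood at 98.1 ± 7.28 CPM (counts scaled to library size, SD, n = 5) in WT livers and at 17.9 ± 2.36 CPM in TALKO livers, which is 18.3% of the WT mean. ARKO livers had 91.6 ± 19.3 CPM and DKO livers 20.95 ± 1.17 CPM (SD, n = 5 each). Every TALKO and DKO library, at 14.2 to 22.7 CPM, lay below every WT and ARKO library. Taldo1 fell in TALKO against WT (log2 fold change -2.45, SE 0.13, adjusted p = 8.3e-10, edgeR) and in DKO against ARKO (-2.13, SE 0.13, adjusted p = 9.3e-09). One library went partly against its label: the library labelled ARKO replicate 1 had 57.4 CPM of Taldo1, whereas the other 4 ARKO libraries had 96.8 to 103.5 CPM. The estimates for Akr1b3 (chromosome 6, 34302434 to 34317478) were low in all groups, with 1.90 ± 0.750 CPM in WT, 1.31 ± 0.183 in TALKO, 2.32 ± 1.08 in ARKO and 2.09 ± 1.18 in DKO livers (SD, n = 5). These estimates did not differ in ARKO against WT (log2 fold change 0.29, SE 0.36, adjusted p = 0.841) or in DKO against TALKO (0.68, SE 0.36, adjusted p = 0.497). Reads of Akr1b3 are shared with the pseudogene Gm6644, since the sum of both estimates was within 0.01 of a whole number in 20 of 20 libraries. In most libraries Akr1b3 was given 14.4% of that sum, so its values follow the split of shared reads and are not a measured level. The part of Akr1b3 that was deleted is not given in the sources used here. The level of Akr1b3 therefore checks nothing on the aldose reductase labels, and no measured value here shows the deletion. The gene model Gm3893, chosen after its values were seen, stood at no more than 0.149 CPM in every ARKO and DKO library. It stood at 2.68 CPM or more in every WT and TALKO library. That sorts the libraries by label but does not show what was deleted.

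**Figure D1:**
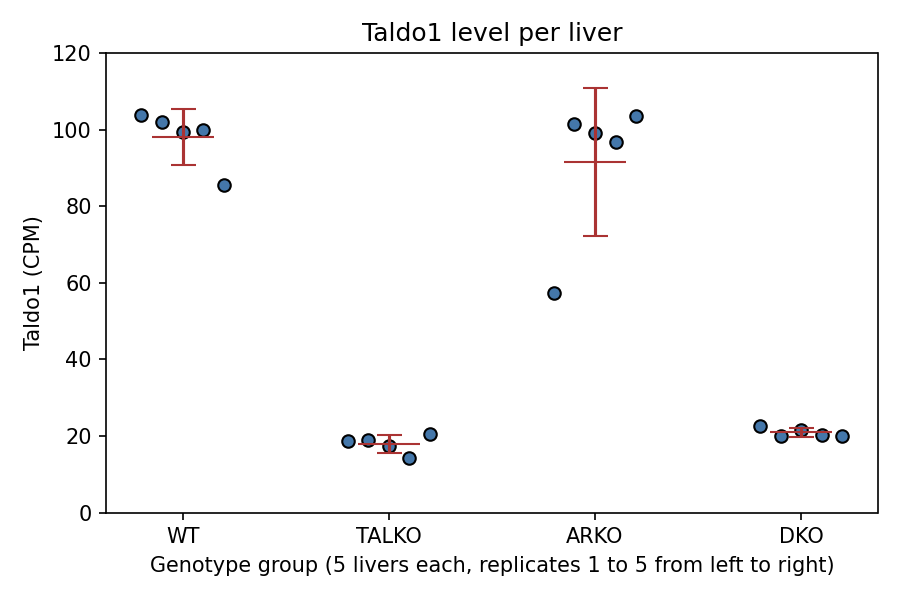
Taldo1 in CPM (vertical axis, linear from 0) for each of the 20 livers by genotype group; points are livers, and bars with whiskers are the mean and SD of the 5 livers. The TALKO and DKO livers lie at 14.2 to 22.7 CPM, and the library labelled ARKO replicate 1 lies at 57.4 CPM, below the other 4 ARKO livers.

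The first comparison, TALKO against WT, asks what the loss of transaldolase changed in livers that kept aldose reductase. Of 19 genes that female mouse livers normally express above male livers 15 fell, and of 15 genes that male livers normally express above female livers 7 rose. Of 24 targets of NRF2, the transcription factor of the antioxidant response, 16 rose, as did 8 of 22 genes of glycolysis and 17 of 31 of oxidative phosphorylation. Gstp1, a glutathione transferase (chromosome 19, 4035407 to 4037985), stood at 497 ± 111 CPM against 135 ± 31.7 CPM in WT (SD, n = 5). Of 13028 genes, 468 were higher and 361 lower in TALKO livers (edgeR, Benjamini-Hochberg, threshold 0.05), 134 and 153 of them by at least 2-fold.

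Of the 19 tested female-biased liver genes 15 fell, 0 rose and 4 did not pass (17 and 0 with p adjusted over the list alone), with a median log2 fold change of -2.82 (camera, adjusted p = 6.1e-22, adjusted p = 0.0048 with an estimated correlation). Sult2a1, a hydroxysteroid sulfotransferase, fell by 6.08 on the log2 scale (SE 0.88, adjusted p = 3.5e-04, edgeR), Sult3a1 by 6.42 (SE 1.01, adjusted p = 6.6e-04) and the P450 gene Cyp3a41a (chromosome 5, 145694049 to 145720136) by 6.31 (SE 1.15, adjusted p = 0.0019), from 2147 ± 605 to 27.3 ± 50.3 CPM (SD, n = 5). That TALKO mean rests on TALKO replicate 1, with 117 CPM of Cyp3a41a, as the other 4 TALKO libraries had 2.45 to 8.10 CPM. Cyp17a1, the steroid 17-alpha-hydroxylase (chromosome 19, 46667165 to 46673172), fell by 2.99 (SE 0.47, adjusted p = 6.5e-04), from 113 ± 65.9 to 14.4 ± 7.99 CPM. Outside that list, Sult2a3 fell by 7.46 (SE 0.92, adjusted p = 1.0e-04) and Cyp3a44 by 6.10 (SE 0.82, adjusted p = 2.4e-04). Of 15 male-biased genes 7 rose and 0 fell (10 and 0 adjusted over the list alone). Camera on male-biased genes gave adjusted p = 3.9e-14, and adjusted p = 0.0488 with an estimated correlation. Cyp7b1, the oxysterol 7-alpha-hydroxylase (chromosome 3, 18071950 to 18243338), rose from 26.9 ± 4.43 to 139.8 ± 30.005 CPM (log2 fold change 2.38, SE 0.22, adjusted p = 3.8e-06), Cyp2d9 rose by 3.28 (SE 0.31, adjusted p = 4.1e-06) and Mup20, a major urinary protein also called darcin, by 4.60 (SE 0.76, adjusted p = 9.2e-04). TALKO replicate 1 had 3383 CPM of Mup20, and the other TALKO libraries had 222 to 971 CPM. Outside the male-biased list, other genes of the Mup family fell. They were Mup15 (-7.22, SE 1.41, adjusted p = 0.0034), Mup17 (-6.30, SE 1.20, adjusted p = 0.0028) and Mup19 (-5.46, SE 1.07, adjusted p = 0.0034). Cyp4a12a had 302 counts over the 5 TALKO libraries and 1 count over the 5 WT libraries, a ratio of 281 with a 95% interval of 49.99 to 11120 that covers counting error only. The Cyp3a, Sult2a, Cyp4a12 and Mup families hold near-identical copies that share reads, so the split between their members is uncertain. Xist did not differ (log2 fold change -0.04, SE 0.13, adjusted p = 0.904), and Y-linked genes stayed at or below 0.380 CPM of the unscaled library total in every TALKO and DKO library.

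NRF2 targets moved in one direction: 16 of 24 rose, 0 fell and 8 did not pass (17 and 0 adjusted over the list alone). Camera on NRF2 targets gave adjusted p = 5.85e-20, and adjusted p = 0.0182 with an estimated correlation. Gstp1 rose by 1.88 on the log2 scale (SE 0.17, adjusted p = 1.7e-06, edgeR), Gsta1 by 5.15 (SE 0.77, adjusted p = 4.2e-04), Gstm1 by 1.55 (SE 0.22, adjusted p = 2.8e-04) and Htatip2 by 0.90 (SE 0.13, adjusted p = 2.7e-04). The Gsta and Gstm genes are families of similar copies, so their split is uncertain too. Among 23 antioxidant enzymes and paraoxonases, 2 rose, 1 fell and 20 did not pass (2 and 1 adjusted over the list alone). Camera on antioxidant enzymes gave adjusted p = 0.188. Gpx4, the lipid hydroperoxide peroxidase, rose by 0.44 (SE 0.07, adjusted p = 7.5e-04), and Pon1, the paraoxonase of high-density lipoprotein, fell by 0.77 (SE 0.13, adjusted p = 0.0010).

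In sugar metabolism, 8 of 22 glycolysis genes rose, 0 fell and 14 did not pass (11 and 1 adjusted over the list alone). Camera on glycolysis gave adjusted p = 1.3e-05, and adjusted p = 0.0542 with an estimated correlation. Gpi1, glucose-6-phosphate isomerase (chromosome 7, 34201330 to 34230336), rose from 86.3 ± 12.8 to 151 ± 15.0 CPM (log2 fold change 0.81, SE 0.09, adjusted p = 6.5e-05, edgeR), and Eno1, an enolase, rose by 1.01 (SE 0.17, adjusted p = 0.0011). The list of polyol, fructose and uronate metabolism had 3 of 15 genes up and 0 down (4 and 0 adjusted over the list alone, camera adjusted p = 0.0026, adjusted p = 0.149 with an estimated correlation), among them Aldob, the liver aldolase (0.52, SE 0.10, adjusted p = 0.0030). Gluconeogenesis had 1 of 12 up, Fbp1 (1 and 0 adjusted over the list alone). Camera on gluconeogenesis gave adjusted p = 0.0077, and adjusted p = 0.367 with an estimated correlation. In the pentose phosphate pathway 2 of 13 rose and 0 fell (2 and 0 adjusted over the list alone). Camera on the pentose phosphate pathway gave adjusted p = 0.145. One of them was Tkt, transketolase, the partner enzyme of transaldolase (0.46, SE 0.10, adjusted p = 0.0078).

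Of 31 nuclear-encoded genes of oxidative phosphorylation 17 rose, 0 fell and 14 did not pass (29 and 0 adjusted over the list alone). Camera on oxidative phosphorylation gave adjusted p = 3.3e-17, and adjusted p = 0.149 with an estimated correlation. The steps were small: Atp5o rose by 0.50 (SE 0.08, adjusted p = 0.0010, edgeR) and Cox4i1 by 0.36 (SE 0.07, adjusted p = 0.0039). The median of 72 ribosomal protein genes, another class of short abundant transcripts, stood at 0.21 in the same contrast. Of 27 PPARA targets and genes of fatty acid oxidation 3 fell and 0 rose (9 and 0 adjusted over the list alone). Camera on PPARA targets gave adjusted p = 1.5e-08, and adjusted p = 0.381 with an estimated correlation. They included Vnn1, pantetheinase (-3.10, SE 0.74, adjusted p = 0.015), and Fabp1, the liver fatty acid binding protein (-1.09, SE 0.26, adjusted p = 0.017). Fatty acid synthesis had 2 of 18 up and 0 down (3 and 0 adjusted over the list alone, camera adjusted p = 0.0076), one being Me1, the cytosolic malic enzyme (1.31, SE 0.30, adjusted p = 0.010). That list gave adjusted p = 0.668 with an estimated correlation and 0.0506 without WT replicate 2. Of 23 xenobiotic cytochromes P450 and their regulators 8 fell and 2, Cyp2c55 and Cyp3a11, rose (9 and 4 adjusted over the list alone). Camera on P450 genes gave a fall with adjusted p = 5.1e-04, and adjusted p = 0.367 with an estimated correlation. The female-biased list holds 5 of its members. Cyp2c37, which it does not hold, fell by 1.89 (SE 0.32, adjusted p = 0.0010).

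Among 17 fetal and liver cancer-associated genes 5 rose, 1 fell and 11 did not pass (8 and 1 adjusted over the list alone). Camera on fetal genes gave adjusted p = 5.1e-04, and adjusted p = 0.199 with an estimated correlation. H19, an imprinted fetal long non-coding RNA, rose by more than most named genes (log2 fold change 8.17, SE 1.10, adjusted p = 2.4e-04, edgeR), from 3.42 ± 3.75 to 917 ± 699 CPM (SD, n = 5). It lies on chromosome 7 at 142575529 to 142578143, within 10 Mb of Taldo1, where 6 of 106 tested genes were called (Fisher's exact test against the rest of the genome, two-sided p = 1). A count over that window cannot tell whether H19 itself moved with a segment carried along with Taldo1, which was not tested. Spink1, a trypsin inhibitor, had 165 counts over the TALKO libraries and 2 over the WT libraries (ratio 76.7, 95% counting interval 20.9 to 638), and Cbr3, which the NRF2 list also holds, rose by 2.63 (SE 0.41, adjusted p = 6.7e-04). The scavenger receptor gene Scara5 rose by 5.14 (SE 0.80, adjusted p = 6.5e-04) and the protease gene Tmprss4 by 3.93 (SE 0.68, adjusted p = 0.0013). Of 21 interferon-stimulated genes 6 fell and 0 rose (10 and 0 adjusted over the list alone). Camera on interferon-stimulated genes gave adjusted p = 1.8e-06, and adjusted p = 0.376 with an estimated correlation. Kupffer cell and macrophage markers had 1 of 21 down, Timd4 (10 and 0 adjusted over the list alone). Camera on macrophage markers gave adjusted p = 5.3e-04, and adjusted p = 0.639 with an estimated correlation. The call of Timd4 was lost without any 1 of WT replicates 2 and 4 and TALKO replicates 1, 2, 3 and 5 (highest adjusted p = 0.126, without WT replicate 2). In iron handling, 2 of 14 rose and 1 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.363); Ftl1, the ferritin light chain, rose by 0.86 (SE 0.12, adjusted p = 2.5e-04).

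The other lists did not pass in this comparison (camera). Bile acid synthesis and transport (18 genes, adjusted p = 0.623) had 1 gene up, Cyp7b1; its median was -0.10, its mean 0.12 and its test pointed up. The integrated stress and unfolded protein responses had 1 of 22 genes up (adjusted p = 0.386), the acute phase 1 of 21, Saa3 (adjusted p = 0.464; median -0.01, mean 0.23), and cholangiocyte markers 1 of 9, Spp1 (adjusted p = 0.188). Pericentral and beta-catenin targets had 1 of 20 down, Notum (adjusted p = 0.241), and periportal genes 1 of 14 up and 1 down, Ctsc (adjusted p = 0.267). Erythroid markers had 1 of 7 up, Alas2 (adjusted p = 0.368), and adipose markers 1 of 4 (adjusted p = 0.623; median -0.06, test up). Spp1 lost its call without any 1 of WT replicates 2, 4 and 5 and TALKO replicate 4 (highest adjusted p = 0.0685, without WT replicate 4). There were 0 calls among genes of cholesterol synthesis (adjusted p = 0.623), the cell cycle (0.715; median 0.03, mean -0.04), p53 targets (0.742), the circadian clock (0.341), immediate-early genes (0.742), and markers of stellate cells (0.337), neutrophils (0.288), T and NK cells (0.147), B and plasma cells (0.341) and endothelium (0.623; median -0.04, mean 0.02), and among hepatocyte secreted proteins (0.623). Adjusted over the list alone, the acute phase had 3 genes up and 1 down, cholangiocyte markers 2 up, pericentral targets 3 down, periportal genes 3 up and 2 down, and T and NK cell markers 2 down; the counts of the other lists in this paragraph were the same adjusted over the list alone. Over all 35 lists, 13 passed with the preset correlation and 3 (female-biased, male-biased and NRF2) with an estimated one. All 106 called members of the lists had every TALKO library on the called side of the WT mean. The count of called genes was 474 without TALKO replicate 1, 525 without TALKO replicate 2 and 532 without WT replicate 4, and 353 with WT replicates 1 and 2, TALKO replicate 1 and the library labelled ARKO replicate 1 left out together; 53 of the 71 named calls held without any single library.

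The same loss of transaldolase was next compared in livers without aldose reductase, DKO against ARKO. In libraries that the first comparison did not use, 9 of 19 female-biased genes fell, and 11 of 24 NRF2 targets, 4 of 22 genes of glycolysis and 11 of 31 of oxidative phosphorylation rose. The ARKO group includes the library labelled ARKO replicate 1, in which Taldo1 was low. Gstp1 stood at 512 ± 45.8 CPM in DKO and 160 ± 22.0 CPM in ARKO livers (SD, n = 5), and Cyp7b1 at 177 ± 63.4 against 40.5 ± 9.36 CPM. Mtnr1a, a melatonin receptor gene (chromosome 8, 45069137 to 45088506), rose from 0.471 ± 0.163 to 4.24 ± 0.647 CPM (log2 fold change 3.12, SE 0.28, adjusted p = 1.9e-06, edgeR). In all, 326 genes were higher and 231 lower in DKO livers (edgeR, Benjamini-Hochberg, threshold 0.05), 93 and 88 of them by at least 2-fold.

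Female-biased genes had 9 of 19 down and 0 up (17 and 0 adjusted over the list alone). Camera on female-biased genes gave adjusted p = 1.7e-19, and adjusted p = 0.0066 with an estimated correlation. Cyp3a41a fell by 8.45 on the log2 scale (SE 1.28, adjusted p = 7.9e-04, edgeR), A1bg by 5.42 (SE 1.04, adjusted p = 0.0046), Sult2a1 by 4.75 (SE 0.86, adjusted p = 0.0031) and Cyp17a1 by 2.89 (SE 0.46, adjusted p = 0.0012). Male-biased genes had 4 of 15 up and 0 down (6 and 0 adjusted over the list alone). Camera on male-biased genes gave adjusted p = 4.2e-04, and adjusted p = 0.302 with an estimated correlation. Its members included Cyp7b1 at 2.12 (SE 0.22, adjusted p = 1.6e-05) and Cyp2d9 at 2.40 (SE 0.30, adjusted p = 1.5e-04). Mup11, a major urinary protein gene outside the lists, fell by 4.21 (SE 0.67, adjusted p = 0.0011). NRF2 targets had 11 of 24 up and 0 down (15 and 1 adjusted over the list alone). Camera on NRF2 targets gave adjusted p = 3.3e-14, and adjusted p = 0.0474 with an estimated correlation. Its members included Gstp1 at 1.67 (SE 0.16, adjusted p = 8.5e-06), the quinone reductase Nqo1 at 1.05 (SE 0.17, adjusted p = 0.0011) and Htatip2 at 0.88 (SE 0.12, adjusted p = 4.8e-04). Glycolysis had 4 of 22 up and 0 down (9 and 0 adjusted over the list alone). Camera on glycolysis gave adjusted p = 6.6e-06, and adjusted p = 0.0474 with an estimated correlation. Its members included Gpi1 at 0.73 (SE 0.09, adjusted p = 1.7e-04). Oxidative phosphorylation had 11 of 31 up and 0 down (21 and 0 adjusted over the list alone, camera adjusted p = 7.0e-13, adjusted p = 0.224 with an estimated correlation), beside a median of 0.27 for the 72 ribosomal protein genes.

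Of the interferon-stimulated genes 6 of 21 fell and 0 rose (14 and 0 adjusted over the list alone, camera adjusted p = 1.3e-11, adjusted p = 0.180 with an estimated correlation); Usp18, a protease that removes ISG15, fell by 1.29 (SE 0.24, adjusted p = 0.0042, edgeR). Fetal and liver cancer-associated genes had 4 of 17 up (7 up and 1 down adjusted over the list alone). Camera on fetal genes gave adjusted p = 1.3e-04, and adjusted p = 0.180 with an estimated correlation. Its members included H19 at 7.13 (SE 1.11, adjusted p = 9.5e-04). In the stress response list 1 of 22 rose, Asns, asparagine synthetase (3.70, SE 0.79, adjusted p = 0.0098; list 7 and 0 adjusted over the list alone, camera adjusted p = 3.3e-05, adjusted p = 0.180 with an estimated correlation). Xenobiotic P450 genes had 3 of 23 down (7 down and 1 up adjusted over the list alone, camera adjusted p = 4.4e-04, adjusted p = 0.279 with an estimated correlation), and gluconeogenesis 1 of 12 up (1 and 0 adjusted over the list alone). Camera on gluconeogenesis gave adjusted p = 0.0033, and adjusted p = 0.245 with an estimated correlation. Cholesterol synthesis passed downwards with 0 of 24 members called over all genes or adjusted over the list alone (camera, adjusted p = 0.0044, adjusted p = 0.892 with an estimated correlation), but not without ARKO replicate 2 (adjusted p = 0.382) or DKO replicate 2 (adjusted p = 0.305). Erythroid markers passed downwards with 1 of 7 up and 1 down (1 and 5 adjusted over the list alone, camera adjusted p = 0.0033, adjusted p = 0.376 with an estimated correlation, adjusted p = 0.0529 without DKO replicate 5). Adipose markers passed upwards with 0 of 4 called (1 and 0 adjusted over the list alone, camera adjusted p = 0.0396, adjusted p = 0.187 with an estimated correlation), but not without ARKO replicate 3 (0.122), DKO replicate 4 (0.0615) or DKO replicate 5 (0.143). Of 35 lists 13 passed here with the preset correlation and 3 with an estimated one (camera). Some lists that passed in TALKO against WT with the preset correlation did not pass here. They were PPARA targets and fatty acid oxidation, fatty acid synthesis, polyol, fructose and uronate metabolism, and Kupffer cell and macrophage markers. Ftl1 rose by 0.79 (SE 0.12, adjusted p = 6.8e-04), Gpx4 by 0.53 (SE 0.07, adjusted p = 3.0e-04), and Pigr, the polymeric immunoglobulin receptor, fell by 0.83 (SE 0.16, adjusted p = 0.0045). Of 67 called list members 64 had every DKO library on the called side of the ARKO mean, and 39 of the 62 named calls held without any single library. The count of called genes was 328 without the library labelled ARKO replicate 1, 345 without DKO replicate 1 and 353 without DKO replicate 3; DESeq2 called 875, and a fit of the 2 groups alone 338.

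**Figure D2:**
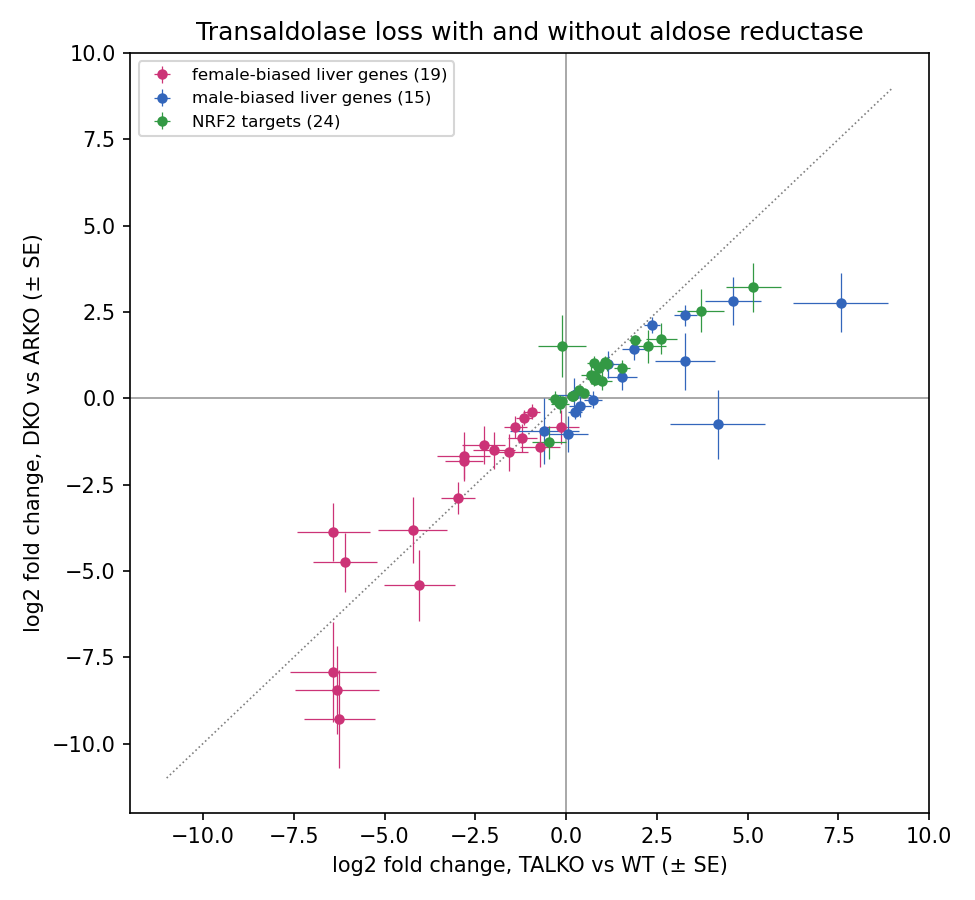
Log2 fold change in TALKO against WT (horizontal axis) and in DKO against ARKO (vertical axis) for the tested genes of 3 lists: 19 female-biased genes, 15 male-biased genes and 24 NRF2 targets; bars are standard errors and the dotted line marks equal changes. The female-biased genes lie mostly at lower left (medians -2.82 and -1.68) and the NRF2 targets at upper right (medians 0.78 and 0.67).

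These comparisons share no library, so their overlap was tested directly. Of the genes called higher in each, 214 were shared where 11.7 were expected by chance (Fisher's exact test, p = 1.0e-245), and of those called lower 134 were shared against 6.40 (p = 3.0e-155); 0 genes were called in opposite directions. Of the 829 genes called in TALKO against WT, 807 had the same sign in DKO against ARKO. Across all 13028 genes the fold changes correlated at Pearson r = 0.70 and Spearman rho = 0.55; genes are not independent replicates. At a threshold of 0.01 the shared genes were 66 higher and 54 lower, and at 0.1 they were 356 and 227.

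Whether the effect of transaldolase loss differed with aldose reductase status was tested by the interaction. It called 0 of 13028 genes with edgeR, and also 0 with DESeq2 and 0 with limma-voom. With edgeR 427 genes had an unadjusted p under 0.05, fewer than chance alone gives, and the smallest adjusted p was 0.9999. Of the genes with the smallest p, Psd4 (log2 difference of effects 0.77, SE 0.17, adjusted p = 0.9999) and Slc2a6 (2.30, SE 0.62), a glucose transporter family member, failed the adjustment, as did Camkmt, Adora1 and Serpine1. Of 35 lists, 11 passed with the preset correlation and 0 with an estimated one (smallest adjusted p = 0.377), and 6 of the 11 lost their call when 1 library was left out. The smallest preset p was that of PPARA targets and fatty acid oxidation, whose effect was higher by a median of 0.52 in the absence of aldose reductase (camera, adjusted p = 5.3e-10, adjusted p = 0.540 with an estimated correlation; 0 members called over all genes or adjusted over the list alone). Male-biased genes had a median of -0.77 (camera, adjusted p = 8.9e-10, adjusted p = 0.377 with an estimated correlation; 0 members called either way). In simulated data the test recovered 10% of 1.5-fold and 43% of 2-fold interactions, and DESeq2 recovered 27% and 63%.

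The joint loss of both enzymes was compared as DKO against WT. In DKO livers 13 of 19 female-biased genes fell, and 13 of 24 NRF2 targets, 7 of 22 genes of glycolysis and 22 of 31 of oxidative phosphorylation rose. Gpi1 stood at 177 ± 11.9 CPM against 86.3 ± 12.8 CPM (SD, n = 5; log2 fold change 1.04, SE 0.09, adjusted p = 1.4e-06, edgeR), and H19 at 160 ± 130 against 3.42 ± 3.75 CPM (5.65, SE 1.0002, adjusted p = 0.0014). In all, 728 genes were higher and 557 lower (edgeR, Benjamini-Hochberg, threshold 0.05), 131 and 170 of them by at least 2-fold. Because this comparison uses the same WT libraries as the first, their overlap was not compared.

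In DKO against WT, 13 of 19 female-biased genes fell and 0 rose (16 and 0 adjusted over the list alone). Camera on female-biased genes gave adjusted p = 4.4e-17, and adjusted p = 0.0079 with an estimated correlation. Cyp3a41b had 3 counts over the 5 DKO libraries and 4090 over the 5 WT libraries, a ratio of 1396 (95% counting interval 477 to 6770), and Sult2a1 fell by 7.31 on the log2 scale (SE 0.95, adjusted p = 8.4e-05, edgeR). Male-biased genes had 6 of 15 up and 0 down (7 and 1 adjusted over the list alone). Camera on male-biased genes gave adjusted p = 3.2e-07, and adjusted p = 0.182 with an estimated correlation. Its members included Cyp7b1 at 2.71 (SE 0.23, adjusted p = 4.6e-07). NRF2 targets had 13 of 24 up and 0 down (17 and 1 adjusted over the list alone). Camera on NRF2 targets gave adjusted p = 4.4e-17, and adjusted p = 0.0378 with an estimated correlation. Its members included Gstp1 at 1.93 (SE 0.17, adjusted p = 7.0e-07), Gsr, glutathione reductase, at 0.61 (SE 0.08, adjusted p = 7.9e-05) and Htatip2 at 1.23 (SE 0.13, adjusted p = 8.0e-06). Oxidative phosphorylation had 22 of 31 up and 0 down (26 and 0 adjusted over the list alone). Camera on oxidative phosphorylation gave adjusted p = 3.2e-16, and adjusted p = 0.182 with an estimated correlation. Its members included Cox4i1 at 0.45 (SE 0.07, adjusted p = 6.2e-04), beside a median of 0.21 for the ribosomal protein genes. Glycolysis had 7 of 22 up and 1 down, Hk2 (11 and 1 adjusted over the list alone). Camera on glycolysis gave adjusted p = 1.4e-05, and adjusted p = 0.0625 with an estimated correlation. Its members included Pgam1 at 0.74 (SE 0.11, adjusted p = 3.0e-04) and Eno1 at 1.05 (SE 0.17, adjusted p = 7.1e-04). Polyol and fructose metabolism had 3 of 15 up (4 and 0 adjusted over the list alone). Camera on polyol metabolism gave adjusted p = 0.0012, and adjusted p = 0.139 with an estimated correlation.

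Interferon-stimulated genes had 8 of 21 down and 0 up in DKO against WT (15 and 0 adjusted over the list alone, camera adjusted p = 6.1e-09, adjusted p = 0.280 with an estimated correlation); Isg15 fell by 0.87 (SE 0.20, adjusted p = 0.0093, edgeR) and Usp18 by 1.06 (SE 0.24, adjusted p = 0.0085). The stress response list had 2 of 22 up, Pdia4 and Trib3 (4 and 1 adjusted over the list alone, camera adjusted p = 0.0036, adjusted p = 0.395 with an estimated correlation); Pdia4 lost its call without any 1 of WT replicates 1, 2, 4 and 5 and DKO replicates 2 and 3 (highest adjusted p = 0.0968, without DKO replicate 2). Gluconeogenesis had 3 of 12 up (3 and 0 adjusted over the list alone, camera adjusted p = 0.0187, adjusted p = 0.395 with an estimated correlation), but the list did not pass without WT replicate 2 (0.0573) or DKO replicate 5 (0.0806). Antioxidant enzymes had 2 of 23 up (2 and 0 adjusted over the list alone, camera adjusted p = 0.0187, adjusted p = 0.395 with an estimated correlation), but the list did not pass without WT replicate 3 (0.0697), DKO replicate 1 (0.0550) or DKO replicate 4 (0.0573). Among lists that did not pass, Cyp8b1, the sterol 12-alpha-hydroxylase of bile acid synthesis, rose by 2.03 (SE 0.45, adjusted p = 0.0065), Ftl1 rose by 1.11 (SE 0.12, adjusted p = 1.2e-05), and Hamp2, a paralog of the iron hormone hepcidin, fell by 2.68 (SE 0.60, adjusted p = 0.0076). Of 105 called list members 98 had every DKO library on the called side of the WT mean, and 50 of the 65 named calls held without any single library. The count was 589 in a fit of the 2 groups alone and 759 with the 4 doubted libraries left out together.

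The loss of aldose reductase alone was asked in ARKO against WT, where few genes were called. An unadjusted p under 0.05 was reached by 1353 of 13028 genes (edgeR), more than the share of 0.05 that chance alone gives. In simulated data the test recovered 36% of 1.5-fold changes here, so few calls do not show that few genes changed. The ARKO group again includes the library labelled ARKO replicate 1. Ces1b, a carboxylesterase (chromosome 8, 93056728 to 93080017), fell from 265 ± 39.7 to 74.7 ± 8.37 CPM (SD, n = 5; log2 fold change -1.82, SE 0.19, adjusted p = 6.2e-05, edgeR). Lnx1, a ubiquitin ligase gene (chromosome 5, 74592447 to 74702912), fell from 4.81 ± 1.51 to 0.294 ± 0.153 CPM (-3.95, SE 0.46, adjusted p = 1.7e-04), and Trhde, the gene of an enzyme that degrades thyrotropin-releasing hormone (chromosome 10, 114398823 to 114802307), from 14.8 ± 4.94 to 1.15 ± 0.730 CPM (-3.62, SE 0.43, adjusted p = 1.7e-04). Klhdc4, a kelch-domain gene (chromosome 8, 121796313 to 121829569), rose from 9.28 ± 0.746 to 16.4 ± 2.26 CPM (0.83, SE 0.11, adjusted p = 8.1e-04). In all, 13 genes were higher and 22 lower (edgeR, Benjamini-Hochberg, threshold 0.05), 8 and 12 of them by at least 2-fold.

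Sult2a6 had 1026 counts over the ARKO libraries and 2 over the WT libraries (ratio 572, 95% counting interval 158 to 4730). Sult2a3, of the same family on chromosome 7, fell by 3.15 on the log2 scale (SE 0.66, adjusted p = 0.0435, edgeR). Reads are shared within the Sult2a family, so the split between these genes is uncertain. Ces1g rose by 1.89 on the log2 scale (SE 0.33, adjusted p = 0.012, edgeR), opposite to Ces1b of the same family. Galns, a lysosomal sulfatase, rose by 1.04 (SE 0.16, adjusted p = 0.0060), and Atp10d, a phospholipid transporter gene annotated as a polymorphic pseudogene, fell by 1.49 (SE 0.24, adjusted p = 0.0080). Of the tested list members 1 was called, the cyclin gene Ccne2, which lost its call without any 1 of WT replicates 2 and 5, the library labelled ARKO replicate 1 and ARKO replicates 2, 3 and 4 (highest adjusted p = 0.108, without the library labelled ARKO replicate 1). Of 35 lists 15 passed with the preset correlation and 0 with an estimated one (smallest adjusted p = 0.582), and 9 of the 15 lost the call without at least 1 library. The smallest preset p was that of pericentral and beta-catenin targets (median 0.45; 0 of 20 called over all genes or adjusted over the list alone, camera adjusted p = 3.4e-06, adjusted p = 0.582 with an estimated correlation). Of the 20 named and called genes, which were named only where every ARKO library lay on the called side of the WT mean, 11 held without any single library. The count was 21, 23, 19 and 19 without the library labelled ARKO replicate 1 and ARKO replicates 3, 4 and 5 in turn; DESeq2 called 107, a fit of the 2 groups alone 14, and the fit without the 4 doubted libraries 13.

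The loss of aldose reductase in livers already without transaldolase was compared as DKO against TALKO. Of the 20 genes named and called in ARKO against WT, 7 were called here in the same direction (Atp10d, Cdk5rap1, Ces1b, Galns, Klhdc4, Lnx1 and Trhde) and 13 did not pass, among them Sult2a6 (adjusted p = 0.354, edgeR), Ces1g (adjusted p = 0.195) and Ccne2 (adjusted p = 0.984). Ces1b stood at 86.4 ± 23.0 CPM in DKO against 237 ± 68.4 in TALKO livers, Lnx1 at 0.251 ± 0.180 against 5.60 ± 2.42, Trhde at 0.261 ± 0.140 against 12.3 ± 7.18 and Klhdc4 at 17.1 ± 1.38 against 8.89 ± 1.32 CPM (SD, n = 5). In edgeR, Trhde fell by 5.50 on the log2 scale (SE 0.53, adjusted p = 1.0e-05), Lnx1 by 4.39 (SE 0.46, adjusted p = 2.8e-05) and Ces1b by 1.46 (SE 0.19, adjusted p = 4.4e-04), and Klhdc4 rose by 0.95 (SE 0.11, adjusted p = 1.1e-04). Atp10d fell by 1.85 (SE 0.24, adjusted p = 3.0e-04), Adam11 by 1.43 (SE 0.20, adjusted p = 9.8e-04), and Cdk5rap1 rose by 1.20 (SE 0.21, adjusted p = 0.013). In all, 17 genes were higher and 26 lower (edgeR, Benjamini-Hochberg, threshold 0.05), 4 and 18 of them by at least 2-fold, and 0 list members were called.

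PPARA targets and fatty acid oxidation had 12 of 27 members up adjusted over the list alone and 0 over all genes (median 0.47; camera, adjusted p = 7.0e-09, adjusted p = 0.783 with an estimated correlation), and pericentral targets 5 of 20 adjusted over the list alone and 0 over all genes (median 0.40; camera, adjusted p = 8.0e-07, adjusted p = 0.783 with an estimated correlation). Of 35 lists 12 passed with the preset correlation and 0 with an estimated one, and 7 of the 12 lost the call without at least 1 library. Of the 20 named and called genes, each named only where every DKO library lay on the called side of the TALKO mean, 8 held without any single library. The count rose to 90 without DKO replicate 3 and was 26, 24, 21 and 19 without TALKO replicates 1, 2, 4 and 5 and 24, 16 and 18 without DKO replicates 1, 2 and 4; DESeq2 called 163 and a fit of the 2 groups alone 18.

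The genes called with aldose reductase loss on both backgrounds were few, and 0 were called in opposite directions. Of those called higher 3 were shared (Cdk5rap1, Galns and Klhdc4) where 0.0170 were expected by chance (Fisher's exact test, p = 5.2e-07), and of those called lower 11 were shared against 0.0439 (p = 1.2e-25); these comparisons share no library. The 11 were Arf5, Atp10d, Ces1b, Ciapin1, Entpd4, Lnx1, Ncl, Nsun7, Trhde, Zfp932 and the gene model Gm3893; those of the 11 outside the rule for named genes were named after their values were seen. Gm3893, a model without a given name on chromosome 4 (42091207 to 42092287), had 345 counts over the WT and 1 over the ARKO libraries (ratio 309, 95% counting interval 55.2 to 12250), and 264 over the TALKO and 2 over the DKO libraries (ratio 126, interval 34.4 to 1042). Of the 35 genes called in ARKO against WT 32 had the same sign in DKO against TALKO. Across all genes the fold changes correlated at Pearson r = 0.42 and Spearman rho = 0.38; genes are not independent replicates. Near Akr1b3, 1 of the 85 tested genes within 10 Mb was called on each background, Arf5 (chromosome 6, 28423560 to 28426602; Fisher's exact test, p = 0.206 and p = 0.246). Nsun7, Limch1, Atp10d and Lnx1 lie in 1 stretch of chromosome 5 from 66259897 to 74702912, and Klhdc4, Aprt and Galns in 1 stretch of chromosome 8 from 121796313 to 122611463. Of these, Limch1 was called in ARKO against WT alone, where it rose while its neighbours fell (DKO against TALKO, adjusted p = 0.258, edgeR). Aprt was called in DKO against TALKO alone (ARKO against WT, adjusted p = 0.0529, edgeR). At a threshold of 0.01 the shared genes were 1 higher and 7 lower, and at 0.1 they were 8 and 18.

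**Figure D3:**
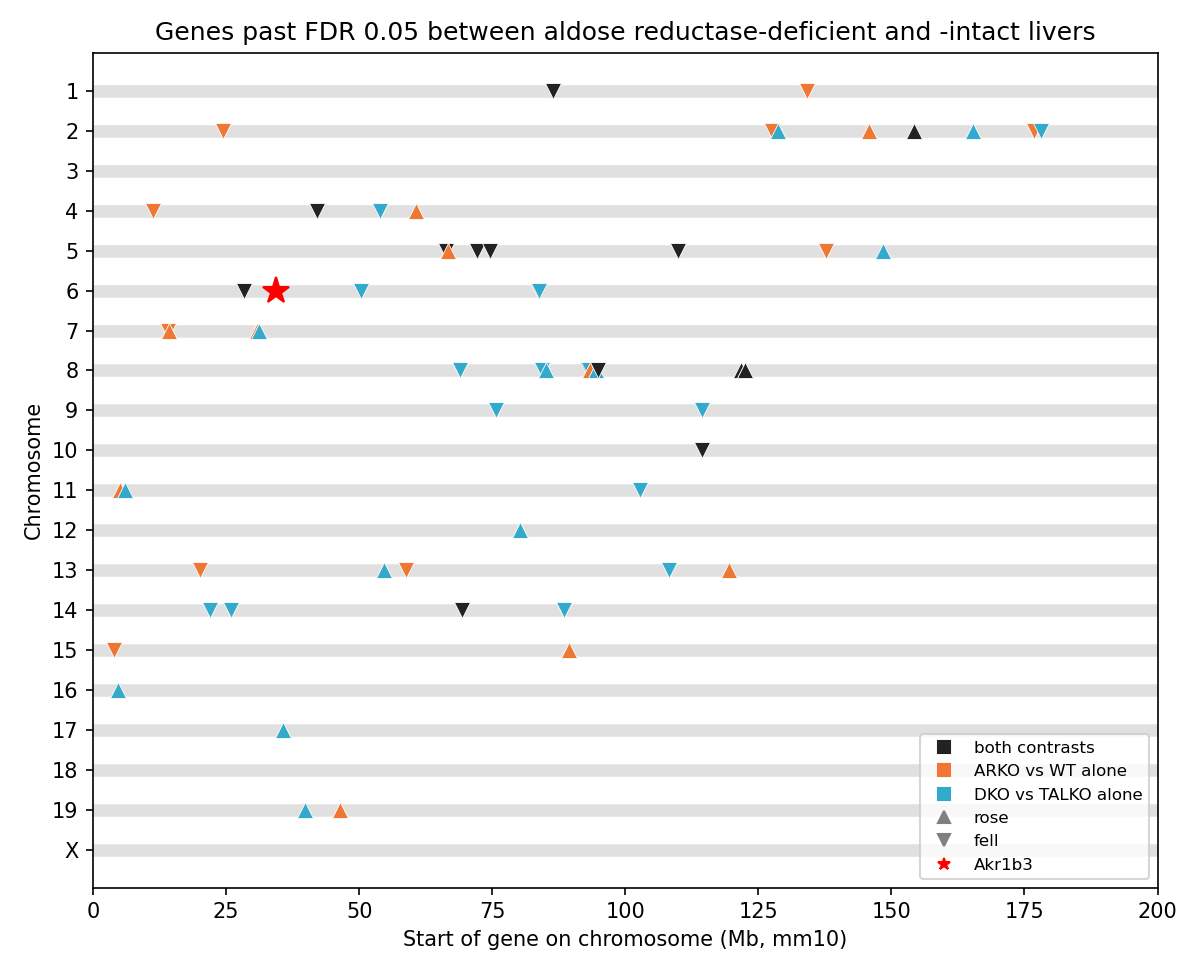
Positions on mm10 (megabases, horizontal axis) of the genes called with aldose reductase loss, one line per chromosome; markers tell genes called in ARKO against WT, in DKO against TALKO and in both, and the star marks Akr1b3. The 64 genes are spread over many chromosomes, with groups of them on chromosomes 5 and 8.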

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

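Among the tests below, those of a wrong sex label, of shared reads, of a linear trend with animal number, of livers of near number paired, of the positions of genes called with aldose reductase loss, of counting error and of 1 intact Taldo1 copy were chosen after the result was seen. The covariate and the regroupings of libraries were chosen before. The mixing test was written before its own outcome, but it addresses a low Taldo1 level that had been seen.

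In 84 groups of 5 values, the highest or lowest library was compared with the other 4, and 18 groups had a library that stood apart. Chance gives about 1 in 20 only for independent, normally distributed values, which these were not shown to be. Where 1 library alone had counts, it stood apart by construction. Taldo1 stood at 85.5 CPM in WT replicate 5 (others 99.4 to 103.8) and at 57.4 CPM in the library labelled ARKO replicate 1 (others 96.8 to 103.5). TALKO replicate 1 had 192 CPM of Cyp7b1 (others 122 to 138), 3383 CPM of Mup20 (others 222 to 971) and 117 CPM of Cyp3a41a (others 2.45 to 8.10). ARKO replicate 3 had 180.4 CPM of Mup20 (others 31.5 to 63.7), 3.95 CPM of H19 (others 0.253 to 0.801) and a TMM factor of 1.07 (others 0.952 to 0.968). Gpi1 stood at 109 CPM in WT replicate 2 (others 76.1 to 85.0) and Lnx1 at 0.560 CPM in ARKO replicate 2 (others 0.178 to 0.273). Gm3893 stood at 9.18 CPM in WT replicate 5 (others 3.21 to 4.19), at 0.0890 CPM in ARKO replicate 4 and at 0.149 CPM in DKO replicate 2, with 0 in the other libraries of the last pair of groups. The 45S ribosomal RNA entry took 0.804% of the counts in WT replicate 1 (others 0.0165% to 0.0268%) and 0.142% in TALKO replicate 1 (others 0.0183% to 0.0261%). Y-linked genes had 5.63 CPM of the unscaled library total in WT replicate 2 (80 counts; others 0 to 0.233), 0.266 in DKO replicate 1 (4 counts; others up to 0.0770) and 0.0658 in ARKO replicate 5 (1 count; others 0).

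Of 19 female-biased liver genes 15 fell in TALKO against WT and 9 in DKO against ARKO, and of 15 male-biased genes 7 and 4 rose (male-biased list in DKO against ARKO, adjusted p = 0.302 with an estimated correlation, camera). A wrong sex label or male tissue among the transaldolase-deficient livers is excluded: Xist changed by -0.0386 (SE 0.13) in TALKO against WT and -0.34 (SE 0.13) in DKO against ARKO, where the female-biased list had medians of -2.82 and -1.68, and Y-linked genes stayed at or below 0.380 CPM of the unscaled library total in each of these libraries. Reads shared between paralogs are excluded as the whole cause in TALKO against WT, where 3 of the 6 female-biased genes outside multigene families (A1bg, Cux2 and Cyp17a1) fell (median -1.78). A linear trend with animal number is excluded in both comparisons. On the log2 scale it allows a median shift of at most 0.00939 in TALKO against WT and 0.0451 in DKO against ARKO. With the number as a covariate 16 genes fell in TALKO against WT, and 15 without it. As 0 genes followed the number (edgeR), the covariate adds little. Livers of near number were also paired as a block in TALKO against WT (4 of 5 pairs 1 number apart). With the block 14 fell, against 15 in the same 2 groups without it, while 47 genes followed the pairs (edgeR). In DKO against ARKO, with pairs 3 to 59 apart, 12 fell against 8 and 18 followed the pairs. Each pair holds 1 liver of each group, so a day or litter shared within pairs falls on both groups alike. The block could therefore hardly change the count and excludes nothing further. A day or litter that differs between the groups stays open. In DKO against ARKO 2 of the 6 genes fell (median -1.54), where the rule, set after the result was seen, needed at least 3. Those 2, A1bg (-5.42, SE 1.04) and Cyp17a1 (-2.89, SE 0.46), lie outside such families. Their falls argue against shared reads as the whole cause there. For genes inside the families shared reads stay open. A trace of male RNA in WT replicate 2, which had 80 Y-linked counts, was not tested for. It would lower female-biased genes in WT and so shrink their fall in TALKO against WT. Without that library the female-biased list gave adjusted p = 6.4e-24 there (camera), and DKO against ARKO uses no WT library. These values argue against such a trace as the cause. Hormonal control of liver sex bias, a candidate explanation, stays open and was not tested.

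The genes called with aldose reductase loss were the same in part on both backgrounds and lay in groups on some chromosomes. A segment carried along with the targeted gene is excluded as the main cause: at most 2.86% of the called genes lie within 10 Mb of Akr1b3. Segments elsewhere that differ between the mouse lines stay open: in each contrast alone, called genes with a called neighbour within 10 Mb numbered 13 of 35 (random median 10) and 16 of 43 (random median 14), which did not pass (permutation p = 0.209 and 0.361, 10000 draws), but the 14 genes called in both did (7 of 14, random median 2, p = 0.0058), as did the 64 called in either (p = 0.007). Within 5 Mb these p were 0.0708, 0.0603, 0.0064 and 0.0013, and neighbouring copies of 1 family, such as Ces1b, Ces1f and Ces1g, add to them. Line segments may therefore account for part of the genes, and so may the loss of aldose reductase itself; expression in these livers does not separate them.

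The library labelled ARKO replicate 1 had Taldo1 at 57.4 CPM. Counting error is excluded, since the 95% Poisson interval ends at 61.8 CPM, below the lowest other ARKO library at 96.8 CPM. RNA of a transaldolase-deficient liver mixed in is excluded: over 164 genes called up in TALKO against WT, the library lay at -0.0742 on a scale from the other ARKO libraries (0) to DKO (1), where its Taldo1 level needs 0.541 (SD of the other ARKO libraries 0.0868). Its level was 0.947 of the midpoint of the other ARKO libraries and DKO (60.6 CPM), which is the level 1 intact copy may give. That is a hypothesis found and tested on the same data, and the genotype of this liver was not tested.

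The libraries were regrouped at random (100 splits per comparison, the labelled one included). In each of 5 comparisons 1 of 100 splits, the labelled one, called as many genes. That makes chance unlikely but does not exclude it. A share of 1 in 100 is the least that 100 splits can reach, and the 5 comparisons share libraries. TALKO against WT called 829 genes against 3 in the highest other split, ARKO against WT 35 against 2, DKO against WT 1285 against 325, DKO against ARKO 557 against 76 and DKO against TALKO 43 against 4. For the interaction the labelled split called 0 genes, a count that all 100 splits reach by construction, so the splits test nothing there. The highest other split called 729, a structure of the samples: it nearly reverses the transaldolase labels on 1 background, so that both effects add.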

How the results depend on the processing

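The fit without 4 doubted libraries was chosen after the data were seen, and all others before. DESeq2 called 107 genes in ARKO against WT, 875 in DKO against ARKO and 163 in DKO against TALKO (edgeR 35, 557 and 43). A fit of the 2 groups alone called 14 in ARKO against WT, 589 in DKO against WT, 338 in DKO against ARKO and 18 in DKO against TALKO. Without WT replicates 1 and 2, TALKO replicate 1 and the library labelled ARKO replicate 1 together, the counts were 353 in TALKO against WT, 13 in ARKO against WT, 759 in DKO against WT and 307 in DKO against ARKO. Leaving out 1 library at a time gave 474 (without TALKO replicate 1) to 871 (without WT replicate 3) in TALKO against WT, 19 (without ARKO replicate 4) to 39 (without WT replicate 5) in ARKO against WT, 869 (without DKO replicate 4) to 1404 (without DKO replicate 5) in DKO against WT, 328 (without the library labelled ARKO replicate 1) to 717 (without DKO replicate 5) in DKO against ARKO, and 16 (without DKO replicate 2) to 90 (without DKO replicate 3) in DKO against TALKO. Fewer samples lower the power of such fits; beyond that the cause was not tested. The interaction stayed at 0 genes without any of the 20 libraries (edgeR), and DESeq2 and limma-voom called 0. With all libraries 427 genes had an unadjusted p under 0.05 (edgeR), fewer than chance alone gives. The shared genes of transaldolase loss were 66 up and 54 down at a threshold of 0.01 and 356 and 227 at 0.1, and those of aldose reductase loss 1 and 7, and 8 and 18, as the thresholds imply. A block of livers with near animal numbers, in a fit of the 2 groups alone, called 821 genes in TALKO against WT, where that fit without the block called 610 (47.6% of calls up against 54.4%), and 393 in DKO against ARKO, where it called 338 (43.5% against 49.4%); the numbers are not stated to pair livers. The cell cycle list in ARKO against WT reversed without WT replicate 2 (adjusted p = 0.522, camera), the highest of the 10 values with 1 library left out, the lowest being 0.00187 without ARKO replicate 3. RLE factors gave 829, 35, 1287, 562, 45 and 0 genes in the 6 contrasts. Over all alternatives, list calls were kept in 857 cases and lost in 214, fold changes of named genes stayed on their side of the threshold in 3777 and lost their call in 703, and those of Taldo1 and of Akr1b3, which was called in none, stayed on their side in all 184. Depth limits genes with few counts, and with 5 livers per group edgeR recovered 10% of simulated 1.5-fold interactions.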

Other observations

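All values in this part were looked at without a test fixed in advance, and none is offered as an effect of genotype. The share of counts taken by albumin, the main secreted protein of hepatocytes, ran from 8.52% to 15.4% in WT, 7.61% to 10.9% in TALKO, 7.76% to 10.8% in ARKO and 4.69% to 8.32% in DKO libraries, so that every DKO library lay below every WT library. Xist stood 0.34 lower on the log2 scale in DKO than in ARKO livers (log2 fold change -0.34, adjusted p = 0.153, edgeR), which did not pass. Log2 fold changes had a rank correlation with gene length across 12907 genes (genes are not independent replicates) of -0.0658 in TALKO against WT, 0.0061 in ARKO against WT, -0.133 in DKO against WT, -0.175 in DKO against ARKO and -0.119 in DKO against TALKO.

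Akr1b3 made up 25.2% to 29.8% of the summed estimates of Akr1b3 and its pseudogene Gm6644 in WT replicate 4, ARKO replicate 2 and DKO replicates 1 and 3, and 14.4% in each of the other 16 libraries. The sum stood at 11.0 ± 2.61 CPM in WT, 9.09 ± 1.27 in TALKO, 13.6 ± 2.17 in ARKO and 10.4 ± 2.64 in DKO livers (SD, n = 5).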
